A study of Drosera capensis with 12 samples.

How the data were processed

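RNA was sequenced from leaf traps of the Cape sundew in 12 libraries of 4 groups, with 3 libraries each: traps closed after GSH at 100 mM, their mock traps, traps closed on living fruit flies, and their mock traps. Groups were taken from the sample titles. For the fly-closed libraries another label names GSH as the agent, against the title and the sample code, and the title was followed. Per the labels' protocols, libraries were made from total RNA with a kit that adds an index to each sample; sequencing depth and read layout are not given in the sources used here.

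Per the submitters' processing notes, cutadapt, Trimmomatic, RSEM and DESeq2 version 1.16.1 were used, with no role or order given. The deposited table has 397048 features with Trinity-style IDs and no gene names. Although the table is named as RSEM counts, its values are a rescaled signal: in every library, 100% of the deposited values above 0 and below 60 were multiples of the library's sum divided by 1e+08, within 0.0051, while at most 2.25% were whole numbers within 0.005. The deposited signal therefore equals a per-million value, rounded to 2 decimals, multiplied by a library total and divided by 1e+06. This value was taken to be TPM, but the check does not show whether it was corrected for feature length. Which step made the values this way is not given in the sources used here. TPM corrects for feature length, so if the values are TPM, those of short assembly fragments may be inflated. Reads shared between sister features of one assembly component may be divided between them. Neither was tested, and feature lengths were not examined.

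A quasi-likelihood test for counts, with a Wald test for counts as an alternative, had been planned on the assumption that the table held counts. These values are no counts, so neither was used and limma took their place. Its settings, including the pseudocount, the scaling and the translated filter, were fixed only once the values had been seen to be no counts, after a first look at how many features were called under several scalings and pseudocounts. The groups, the comparisons, the threshold and the rule for named features were fixed before the data were examined.

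Each value was divided by its library's sum and multiplied by 1e+06 to give the value called TPM here. Features were tested when they reached 0.526 TPM, which is a value of 10 at the median library sum, in at least 3 libraries; 45503 features in 33442 assembly components did. Libraries were scaled by a trimmed mean of log ratios (30% trimmed from the ratios, 5% from the abundances at each end, no weights). After adding 1, log2 values were fitted with limma version 3.58.1 in R version 4.3.3, in one model of the 4 groups with 8 residual degrees of freedom and moderated variances (trend and robust options). Features with a Benjamini-Hochberg adjusted p below 0.05 were called. The contrasts were each closed group against its mock, the difference between these effects, and mock against mock. The overlap of calls was compared with that of independent lists (the product of the list lengths over the features tested, per direction), and Spearman's rho of the changes was tested over 100 combinations of library splits within the experiments. Single values per library were compared with exact permutation tests.

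The rule for named features took the 2 that rose and the 2 that fell with the largest smaller change of both comparisons, among features called the same way in both, with groups that do not overlap in either and a mean log2 value of at least 3; 911 features that rose and 165 that fell met these conditions. Chance alone gives groups that do not overlap in 10% of features with 3 against 3 libraries. Gene lists prepared before the data were examined could not be applied without gene names.

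The calculation was tested on simulated data for the GSH comparison with 45503 features: 76% of 100 features changed 2-fold and 89% of 100 changed 4-fold were recovered, with 7 false calls. The changed features rose and fell in equal number and all had a mean log2 value of at least 3. Noise was normal, with the same SD for a feature in all groups. The real GSH comparison called 25.8% of features, with larger rises than falls. The simulation therefore does not show how scaling, recovery of low features or false calls behave under such a response. Alternatives covered the scaling, the filter, a fold minimum, a replicate block, removal of features seen with flies alone, which groups entered the fit, and leaving out each library. A pseudocount of 0.1, no scaling, and testing features above 0 in all 12 libraries were added after seeing the data. No reference genome was used here.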

Results

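Leaf traps of the Cape sundew (Drosera capensis), a carnivorous plant that folds its sticky leaves around prey, were profiled by RNA sequencing in 4 groups of 3 libraries. Traps had closed either after glutathione (GSH), a small thiol tripeptide, was applied to the petiole at 100 mM, or after the leaf was fed living fruit flies. Each stimulus had its own unstimulated mock traps, called the GSH mock and the fly mock below. The table held 397048 transcript features of a de novo assembly. Of these, 227782 were above 0 in at least 1 library and 45503 were abundant enough to be tested. The files do not pair the features with gene names, so response classes take the place of gene groups, and 4 features picked by a fixed rule are named by their assembly IDs. The values of a library summed to between 17708300 and 20453100, which is a total of rescaled values, so the read depth behind a single feature is unknown.

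Libraries of the same group resembled each other more than most libraries of different groups. Pearson's r across the tested features, on log2(TPM + 1), ranged from 0.914 to 0.929 within groups and from 0.806 to 0.914 between groups. Features are not independent replicates, so these r values only describe the libraries. The first principal component held 35.0% of the variance and set the 3 GSH-closed libraries apart from the other 9, and the second held 12.3%. The labels do not say that the samples of a group came from separate plants, so the p-values measure the spread between these samples, which may be technical.

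**Figure D1:**
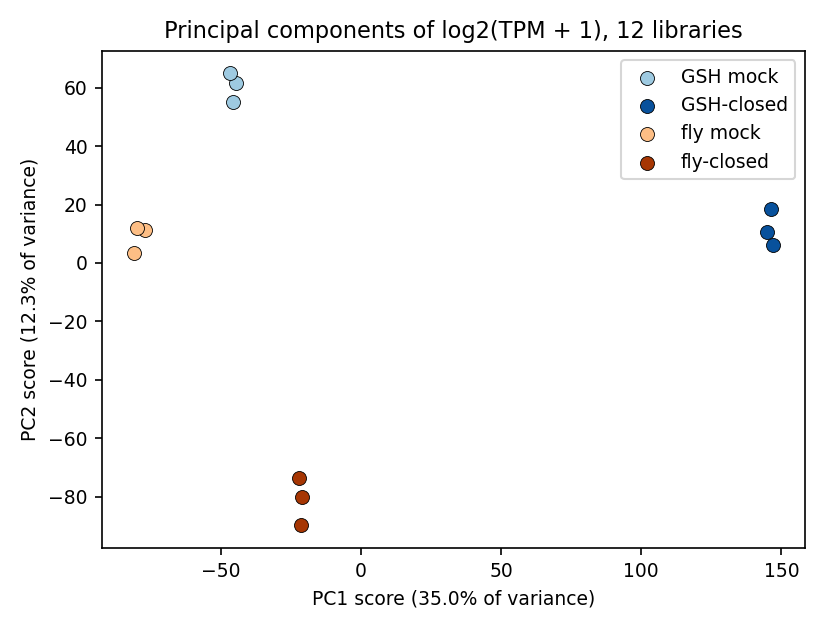
Principal component scores of the 12 libraries on log2(TPM + 1), with 1 point per library, coloured by group; the axes give component scores and the percent of variance held. The first axis (35.0%) parts the GSH-closed libraries from the rest.

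The first comparison asked how the transcriptome of a trap closed by GSH differs from that of its mock. Both directions were common: 11723 of 45503 features (25.8%) differed between GSH-closed and GSH mock traps, 6670 higher and 5053 lower. The features that rose did so by more than those that fell. The median change was 1.23 on the log2 scale among features that rose and -0.63 among those that fell, and 4136 rose while 982 fell by at least 2-fold. At 16-fold or more, 368 features rose and 10 fell. The calls are from limma at a Benjamini-Hochberg adjusted p below 0.05, with changes on the log2(TPM + 1) scale, which understates the change of low features.

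The features that rose held 22.6% ± 0.152 (SD, n = 3) of all TPM in the GSH mock and 45.6% ± 0.310 (SD, n = 3) in the GSH-closed traps. The features that fell went from 22.0% ± 1.07 (SD, n = 3) to 10.6% ± 0.107 (SD, n = 3). These shares move apart in the GSH libraries by the way the sets were chosen; their sizes describe how much of the RNA was involved. The gain was taken in mean TPM without scaling, over those of the 6670 whose mean TPM rose. Some of the 6670 had a lower mean TPM after GSH and were left out of it. The 10 features with the largest gain made up 11.0% of it, and 198 made up 50%. The share of features called higher grew with abundance, from 7.37% of those with a mean log2(TPM + 1) of up to 1 to 29.9% of those over 8, and the share called lower grew from 1.43% to 24.0%. Adding 1 understates the change of low features and makes them harder to call. The trend therefore does not show how often features of each abundance responded.

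A small set of features went from under 1 TPM to at least 10 TPM. After GSH, 130 features were under 1 TPM in all 3 mock libraries and at 10 TPM or more in all 3 closed libraries, and all 130 passed the test as higher. The reverse was seen for 12 features, of which 9 passed as lower. These TPM limits were set after the data had been seen. The read depth behind a feature is unknown, so a value near 10 TPM may rest on few reads. Direction depends on scaling: with no scaling between libraries the GSH calls were 4684 higher and 11790 lower, 28.4% higher in place of 56.9%, because the median change of all tested features then moved from -0.01 to -0.27. With no filter on low values 7695 features were called, of which 4417 were higher.

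The second comparison asked the same of traps closed on living fruit flies. Most features that changed rose: 2531 of 45503 features (5.56%) differed between fly-closed and fly mock traps, 2169 higher and 362 lower. Features that rose had a median change of 1.33 on the log2 scale and features that fell one of -0.42. At least 2-fold, 1419 rose and 87 fell, and at least 16-fold, 68 rose and 2 fell. Among the most abundant features more fell than rose: of those with a mean log2(TPM + 1) over 8, 13 rose (3.85%) and 33 fell (9.76%), while of those up to 1, 729 rose (4.42%) and 86 fell (0.522%). Tested features seen in fly-closed traps alone had a median mean log2 value of 0.41. Of these, 521 were called higher, largely through the filter. Adding 1 also makes low features harder to call. The contrast between abundances therefore does not show how often features of each abundance responded. The features that rose held 1.97% ± 0.0371 (SD, n = 3) of all TPM in the fly mock and 5.32% ± 0.263 (SD, n = 3) in the fly-closed traps, and those that fell went from 4.16% ± 0.0924 to 3.19% ± 0.240 (SD, n = 3). Of the 362 features that fell, 22 made up 50% of the loss, taken in mean TPM without scaling over those whose mean TPM fell. From under 1 TPM in every fly mock library to 10 TPM or more in every fly-closed library went 54 features, of which 53 passed the test, and 2 went the other way, of which 1 passed.

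Of the 2169 features higher after flies, 1602 were above 0 in at least 1 mock library of either experiment, and 1389 of these (86.7%) were also higher after GSH. Another 567 were at 0 in all 6 mock libraries, and 521 of those were at 0 in the GSH-closed libraries too, so that they were seen in fly-closed traps alone and could not be called higher after GSH. Of the remaining 46, which were above 0 in GSH-closed traps, 34 (73.9%) were also higher after GSH. A feature tested at all while at 0 in the 9 libraries without flies must be present in all 3 fly-closed libraries, so 521 of 525 such features passing the test follows largely from the filter. The division by presence in mock libraries was made after the data had been seen. With all 52909 features at 0 in the 9 libraries without flies removed, and TPM, filter and scaling recomputed, 45431 features were tested and 1905 were called after flies, 1558 higher and 347 lower.

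The count after flies fell whichever fly-closed library was left out. It was 1377 without fly-closed replicate 1, 1410 without replicate 2 and 1461 without replicate 3, and 1341 with no filter on low values. Without fly mock replicate 1, 2 or 3 it was 2181, 2100 and 2125. When a fly-closed library is left out, features seen in fly-closed traps alone cannot reach the minimum of 3 libraries.

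**Figure D2:**
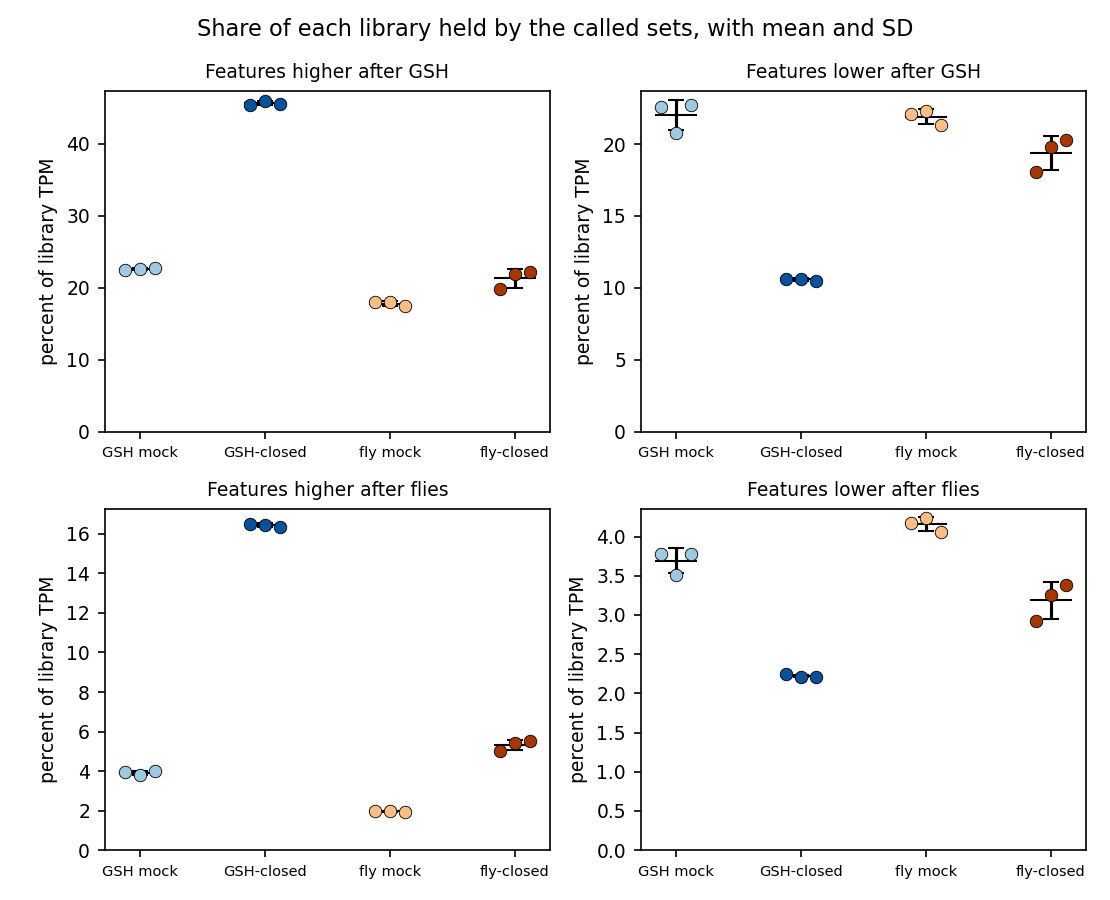
Percent of each library's TPM held by the features called higher or lower after GSH (top) and after flies (bottom), with 1 point per library (n = 3 per group) and the mean with SD as bars, each vertical axis starting at 0. Features called higher after flies held 3.92% of the GSH mock and 16.4% of the GSH-closed libraries.

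The third comparison set the responses side by side; the experiments share no libraries. Most features that rose after flies also rose after GSH. Both stimuli raised 1423 features, 65.6% of those higher after flies and 21.3% of those higher after GSH, where independent lists would share 318. Both lowered 174, 48.1% of those lower after flies, where 40.2 would be shared. The overlap in the same direction was 4.46 times that of independent lists, and with no filter on low values 40.0 times. Both lists share the standard error of each feature and a power that depends on abundance, so unrelated responses could also overlap more than independent lists. Without the filter the expected overlap is divided by 227782 features, 121893 of them above 0 in 1 library only. The 40.0 therefore does not show closer agreement. Among the 1423 features raised by both, the median change was 2.51 on the log2 scale after GSH and 1.17 after flies. Over all 2169 features higher after flies the medians were 1.58 after GSH and 1.33 after flies, and the test of the difference put the GSH effect above for 972 and the fly effect above for 695, of which 503 were seen in fly-closed traps alone.

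The sets chosen in one experiment moved the same way in the libraries of the other. Features called higher after flies held 3.92% ± 0.109 (SD, n = 3) of TPM in the GSH mock and 16.4% ± 0.0943 (SD, n = 3) in GSH-closed traps. Features called higher after GSH held 17.8% ± 0.323 (SD, n = 3) in the fly mock and 21.3% ± 1.29 (SD, n = 3) in fly-closed traps, and features called lower after GSH held 21.9% ± 0.509 and 19.4% ± 1.18 (SD, n = 3). Features called lower after flies held 3.69% ± 0.159 in the GSH mock and 2.22% ± 0.0177 (SD, n = 3) in GSH-closed traps. Shares are not scaled between libraries. Without scaling, the median change of all tested features after GSH was -0.27 on the log2 scale, so part of this fall is not particular to the set. With scaling, the median change after GSH of the features lower after flies was -0.26. In all 4 cases the groups did not overlap, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries allow, also after Benjamini-Hochberg adjustment over the 4.

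Across all tested features the changes after GSH and after flies had a Spearman's rho of 0.27 and a Pearson's r of 0.38. These are correlations across features, which are not independent replicates. The exact permutation p of rho, from 100 combinations of splits within the experiments, was 0.01 (two-sided), the smallest they can give, and the next highest rho of another combination was 0.21 in size. The size of rho depended on which features of low abundance were included, with 0.07 under no filter on low values and 0.48 in the 25% of features with the highest mean.

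**Figure D3:**
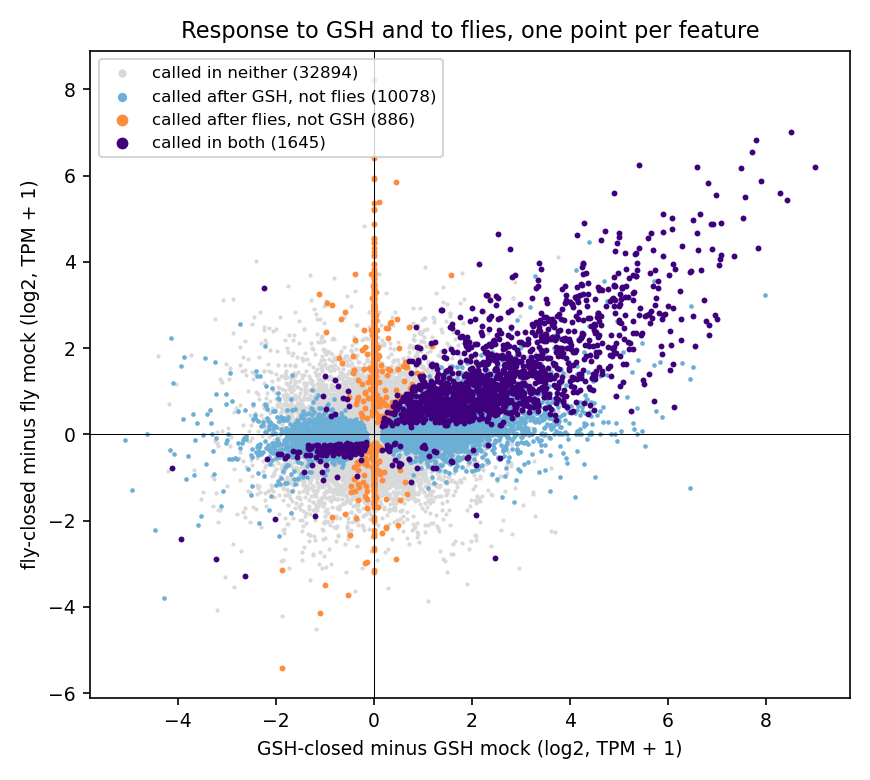
Change after flies (vertical axis) against change after GSH (horizontal axis), both as differences of mean log2(TPM + 1), with 1 point per tested feature, coloured by which comparison called it. Features called in both comparisons lie mostly in the upper right, where 1423 rose after both stimuli; the column of points at 0 on the horizontal axis holds features with no difference in mean between the GSH groups, such as those listed at 0 in all 6 libraries of the GSH experiment, and not all of these passed the test after flies.

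A test of the difference between the responses called 6876 features, with the GSH effect above the fly effect for 4194 and below it for 2682. With no scaling between libraries the count was 10685, with 2779 above and 7906 below, 26.0% above in place of 61.0%. With no filter on low values the count was 3453, with 2440 above and 1013 below. Of the 1423 features raised by both stimuli, 972 rose more after GSH and 15 rose more after flies by this test. Of the features higher after GSH and not called after flies, 3028 differed between the responses and 2183 did not pass that test; among those lower after GSH and not called after flies, 1820 differed and 3047 did not pass. For the features that did not pass, a difference between the stimuli is neither shown nor excluded.

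Of the features higher after flies and not called after GSH, 668 differed between the responses. Of these, 503 were seen in fly-closed traps alone, which leaves 165. Another 66 did not pass the test of the difference. Among the 668, only 32 had a positive change after GSH. Some of the 165 were also undetected in the GSH experiment and fell outside the set of 503 only through a low value in the fly mock. The 165 are therefore not shown to be trap features that respond to flies and not to GSH. Opposite calls were rare: 36 features rose after GSH and fell after flies, and 12 did the reverse.

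The fourth comparison set the mock groups against each other, as the background difference between the experiments. The unstimulated traps were not alike: 4295 features (9.44%) differed, 2573 higher in the GSH mock and 1722 higher in the fly mock. Most of these differences were small, with 841 of at least 2-fold and medians of 0.59 and -0.64 on the log2 scale. With no scaling between libraries the split was 4106 and 1158, 78.0% higher in the GSH mock in place of 59.9%, and with only the mock groups in the fit 2455 features were called. Some response sets differed between the mocks. Features higher after GSH held 22.6% ± 0.152 of TPM in the GSH mock and 17.8% ± 0.323 in the fly mock, and features higher after flies held 3.92% ± 0.109 and 1.97% ± 0.0371 (SD, n = 3). Features lower after flies held less in the GSH mock, 3.69% ± 0.159 against 4.16% ± 0.0924. These gaps had a two-sided exact permutation p of 0.1, the smallest possible, and 0.133 after Benjamini-Hochberg adjustment over 4 sets, while features lower after GSH held 22.0% ± 1.07 and 21.9% ± 0.509 (exact permutation p = 0.9). The fly mock values enter the choice of the sets called after flies, so part of those gaps follows from the choice. All tested features together held 96.0% ± 1.55 of TPM in the GSH mock and 88.0% ± 1.41 in the fly mock (SD, n = 3). This lowers the share of any tested set in the fly mock, and the shares were not corrected for it. The near-equal shares of the features lower after GSH therefore do not show that the mocks were alike in that set. Changes of closed traps were each taken against their own mock.

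The named features show both directions. TRINITY_DN219504_c0_g1 was listed at 0, 3.43 and 0 TPM in the GSH mock and at 526, 536 and 449 TPM in GSH-closed traps, and at 0, 2.1 and 5.38 TPM in the fly mock and 368, 355 and 339 TPM in fly-closed traps. Its change by limma was 8.53 ± 0.67 (SE) on the log2 scale after GSH (adjusted p = 4.59e-06) and 7.01 ± 0.67 after flies (adjusted p = 7.03e-05). Over the alternatives these changes ranged from 8.16 to 10.85 after GSH and from 6.29 to 8.36 after flies, the highest with a pseudocount of 0.1. The size after GSH rests on GSH mock replicate 2, without which the GSH mock is listed at 0. TRINITY_DN7829_c2_g1 rose from 16.9, 0 and 0 TPM to 405, 630 and 410 TPM after GSH, a limma change of 7.81 ± 0.95 (SE, adjusted p = 0.000131). The change ranged from 7.14 to 10.05 over the alternatives, the highest with a pseudocount of 0.1. Its size rests on GSH mock replicate 1, without which the GSH mock is listed at 0. It was listed at 0 in all 3 fly mock libraries, so no fold is given, and at 42.9, 198 and 175 TPM in fly-closed traps (limma adjusted p = 0.00117). It has 7 tested sister features in the same assembly component, with which it may share reads.

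TRINITY_DN360021_c0_g1 fell after GSH from 46.7 ± 21.9 to 7.62 ± 3.2 TPM (SD, n = 3), a limma change of -2.02 ± 0.46 (SE, adjusted p = 0.00839). After flies it went from 41.0 ± 19.2 to 9.58 ± 4.64 TPM, a change of -1.97 ± 0.46 (limma adjusted p = 0.0336), and this call was lost in 6 of 15 alternatives, with adjusted p from 0.0126 to 0.162. TRINITY_DN15927_c2_g1 fell after GSH from 115 ± 31.9 to 40.3 ± 3.93 TPM (SD, n = 3), a limma change of -1.03 ± 0.20 (SE, adjusted p = 0.00333). After flies it went from 138 ± 25.2 to 65.6 ± 15.9 TPM, a change of -1.06 ± 0.20 (limma adjusted p = 0.00941), lost in 3 of 15 alternatives, with adjusted p from 0.00536 to 0.0623. The rule favours features with similar changes in both comparisons, so these 4 do not bear on how the responses differ.

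**Figure D4:**
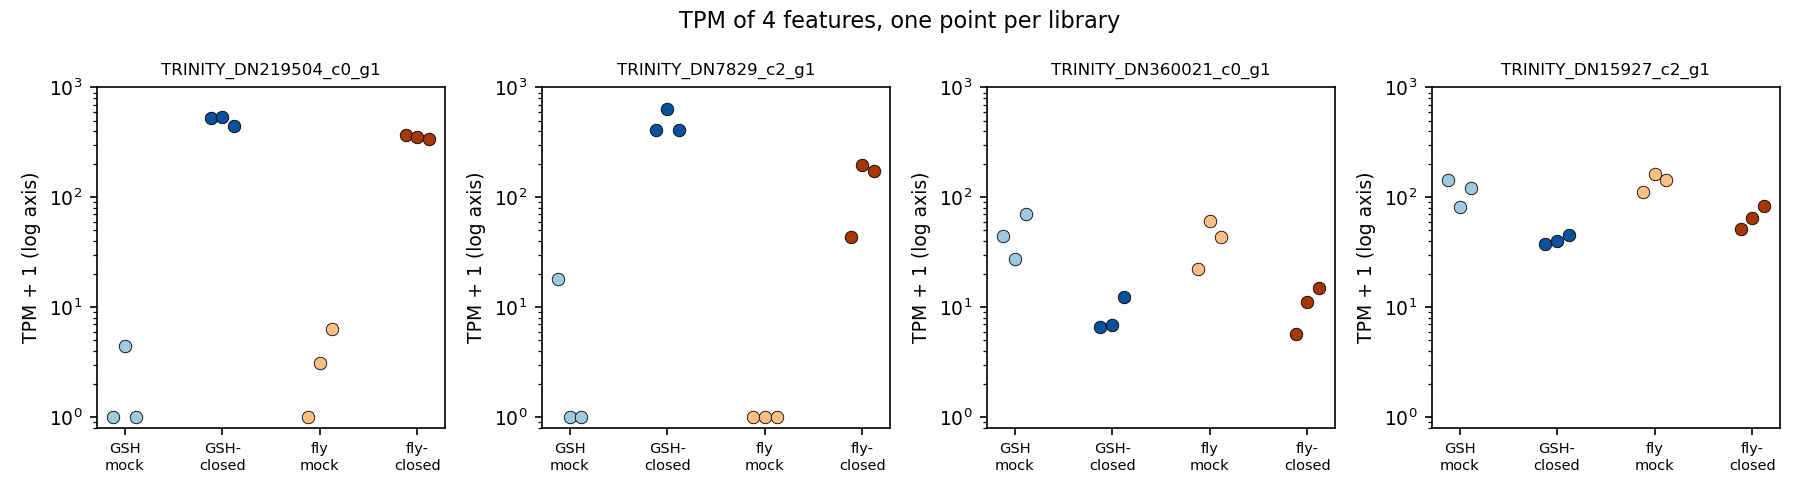
TPM + 1 on a log axis for the 4 named features, with 1 point per library and the groups along the horizontal axis. TRINITY_DN219504_c0_g1 and TRINITY_DN7829_c2_g1 are higher in every closed library than in any mock library of the same experiment, and TRINITY_DN360021_c0_g1 and TRINITY_DN15927_c2_g1 are lower.

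The experiments also differed in how many features were detected. The 6 libraries of the fly experiment had 78654 ± 4774 features above 0 (SD, n = 6) and the 6 of the GSH experiment 61274 ± 1100 (two-sided exact permutation p = 0.00216, 0.00289 after Benjamini-Hochberg adjustment over 4 measures). Features found in a single library held 11.3% ± 3.06 of TPM in the fly experiment and 3.64% ± 1.08 in the GSH experiment (SD, n = 6; exact permutation p = 0.00216). Every library of the fly experiment lay above every library of the GSH experiment in both measures. Library totals did not separate the experiments, with means of 19056100 in the fly experiment and 19014400 in the GSH experiment (exact permutation p = 0.942).

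**Figure D5:**
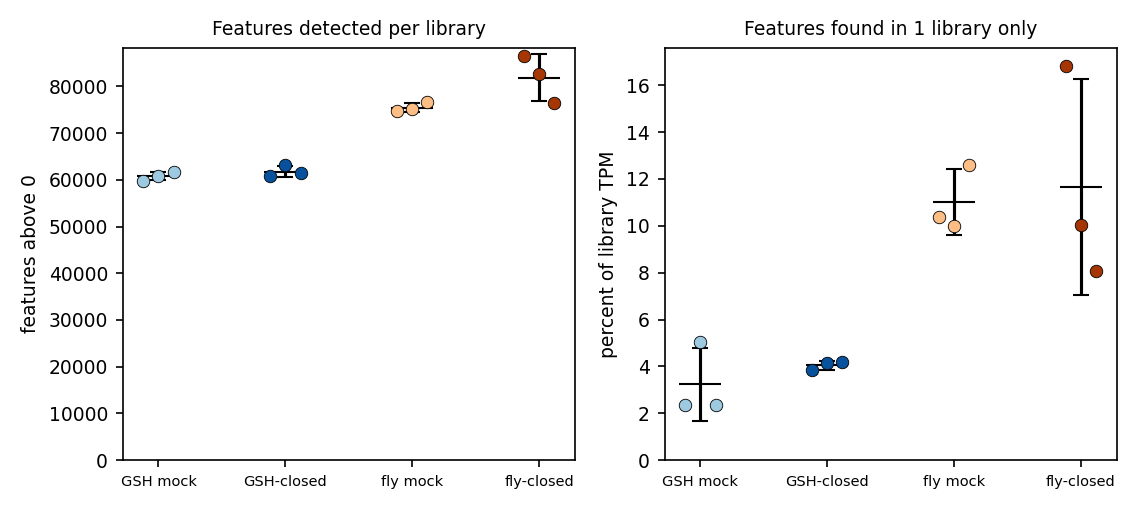
Features above 0 per library (left) and percent of TPM in features found in 1 library only (right), with 1 point per library and the mean with SD of each group (n = 3). The 6 libraries of the fly experiment lie between 74756 and 86499 features and the 6 of the GSH experiment between 59804 and 63088.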

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

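Among the tests in this part, the comparison with other sets of 3 libraries, the comparison with the fly mock set, and the tests of detected features and of the number of calls were chosen only after the result was seen. The test against the GSH-closed set and the splits of the libraries were set before.

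The effects of GSH and of flies differed for 6876 features by the test of the difference itself. Of 100 assignments of the closed and of the mock libraries to the experiments, 7 gave as many, the real one included, and the highest other gave 12752. All 7 kept the closed libraries in their true groups and differed only in the mocks, and assignments that mixed the closed libraries gave at most 26. Because the mocks differ in 4295 features themselves, assignments that exchange mocks are not free of a real difference, and their share neither excludes chance nor argues for it.

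With the scaling used, features called in opposite directions after GSH and after flies numbered 48. Opposite calls in the same fit imply a difference between the effects, so the test of the difference adds nothing for them.

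In all 3 fly-closed libraries and in none of the other 9, 2052 features were above 0, with 0.277% ± 0.0122 (SD, n = 3) of TPM. Chance detection of rare features is argued against, since the highest number for any other of the 220 sets of 3 libraries was 258 (the GSH-closed set), the fly mock set had 252 and the median was 42.5. RNA of the prey or of another organism that came with it is a candidate source: 6.97% of the 2052 had a sister feature of the same assembly component detected outside the group, against 38.4% of the GSH-closed set, a ratio of 0.182 (95% interval 0.146 to 0.227). The reference matters, because the fly mock set had 16.3%, a ratio of 0.428 (0.311 to 0.591), which leaves a source present in the whole fly experiment open, although equal presence there would give the mock set a like number. Both intervals treat features as independent, although features of the same component may share their sister status, and they do not measure the spread between samples. Features found in a single library had such a sister in 5.39% to 12.8% of cases, so a low share does not mark prey RNA alone, and trap genes expressed only with prey stay open.

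The 6 libraries of the fly experiment had 1.28 times as many features above 0 as the 6 of the GSH experiment. Library totals argue against depth, as far as rescaled totals show it, since the mean differed by 0.219%. Features found in a single library are not the whole cause, because the ratio without them was 1.15. A library batch cannot be told apart from the experiments (exact permutation p = 0.00216), because the labels give no batch and each experiment may have been its own; plant state or handling was not tested.

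GSH called 11723 features and flies 2531. In the shared fit of all groups, both comparisons had the same standard error for each feature. A larger spread between the fly libraries could therefore not lower the fly count alone. The median SD within the fly groups was 0.947 times that of the GSH groups, which is no test of that explanation. With only the compared groups in each fit, 9025 features were called after GSH and 2045 after flies. Scaling is argued against by a ratio of calls of at least 4.51 under the 3 scalings tried. The stimulus itself, its dose and the time of sampling, which is not given in the sources used here, may each account for the gap and were not tested.

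Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. In 1 of the 10 splits, the real one, 11723 features were called after GSH (highest other 14); likewise in 1 of 10 for 2531 after flies (highest other 18) and in 1 of 10 for 4295 between the mocks (highest other 20).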

How the results depend on the processing

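The planned Wald test for counts was not run, because the values are no counts. With no scaling, chosen after seeing the data, the larger number of calls was lower and no longer higher after GSH (4684 higher, 11790 lower), and below and no longer above for the difference (2779 and 7906); no named feature changed sign. The correlation rho ranged from 0.07 to 0.48 over 20 alternatives; its exact permutation p was 0.01 in each, the smallest possible, which says nothing about stability. With no filter on low values, where 227782 features were tested, calls were 7695 after GSH, 1341 after flies, 3453 for the difference and 2320 between mocks, and the overlap was 40.0 times that of independent lists. The larger number of features tested lowers the expected overlap, so this ratio does not show closer agreement. Requiring at least 2-fold left 5118, 1506, 3901 and 841. Leaving out 1 library gave 10060 to 11054 calls after GSH, 1377 to 2181 after flies, 5134 to 6780 for the difference, 3066 to 4287 between mocks, a rho of 0.26 to 0.27 and an overlap of 4.29 to 6.03. Among these runs the lowest counts after flies came without a fly-closed library. Features seen in fly-closed traps alone then miss the minimum of 3 libraries. With all of them removed, every library kept and the filter recomputed, 1905 features were called, so they are not shown to make up the whole drop; the cause of the rest was not tested. With only the compared groups in the fit, 2455 features were called between mocks. Of the alternatives chosen after seeing the data, no scaling called 10685 for the difference. The median change of all tested features was then -0.27 after GSH and -0.003 after flies, which moves the difference. Testing only features above 0 in all 12 libraries gave 1514 after flies. By design this drops the 567 features higher after flies that were at 0 in all 6 mock libraries. The cause of the rest was not tested.

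With the replicate number as a block, 11020 features were called after GSH, 2298 after flies, 6168 for the difference and 3724 between mocks, and the overlap was 4.53. The replicate numbers, taken from the titles, showed no pairing: deviations of same-numbered libraries correlated between -0.03 and 0.02, and 2 of 12 libraries correlated best with their own number. The sample codes number the libraries differently, and pairs by code were not tested. The depth behind each feature is unknown, so changes of low features could not be given a counting error.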

Other observations

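The test in this part was set before its result was seen. Sister features, which belong to the same assembly component and may be alleles, isoforms or fragments of related genes, tended to change together after GSH. Of 2993 pairs of called sister features in 1467 components, 64.2% changed in the same direction, against at most 54.8% in 100 shuffles of the directions. Directions independent within components are argued against by this value. Shared reads or split fragments of one transcript may give the same result, so called features should not be read as a number of separate genes.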
